A study of Homo sapiens with 14 samples.

How the data were processed

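MCF-7 cells, an established luminal breast cancer line that carries the estrogen receptor, were the material of all 14 samples, which fall into 7 groups of 2. The labels describe CUT&Tag with an antibody against DHX36, CUT&Tag with BG4 (an antibody that recognises G-quadruplexes) with or without 500 µM IAA, the auxin that triggers degron-tagged protein loss, and AMUC-seq, a nascent RNA method based on 500 µM s4U labelling, with or without IAA. CUT&Tag uses an antibody to bring a transposase to chromatin, so that fragments near the antibody's target are cut and sequenced. A single file was analysed here, the peak list of the DHX36 CUT&Tag group. The 8 AMUC-seq samples and the 4 BG4 samples were not analysed here, so the comparisons with and without IAA or s4U were not made. Groups were taken from the sample titles.

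The build hg38 and the tools Bowtie2, Picard and MACS2 are named, without versions and without the order of the steps, per the submitters' processing notes. STAR and HTSeq are named there too and belong to no file used here. The deposited list has no header and 20 columns, the layout that the IDR program (irreproducible discovery rate) writes for 2 input peak lists. The deposited score was found to be the whole-number part of 125 times the negative log2 of the global IDR, capped at 1000, in 100% of rows. The deposited −log10 values of the local and global IDR reached at most 5, so the lowest IDR printed is 1e-05. The value deposited for each merged peak, called signal here, was the lower of the 2 input lists' values in 100% of rows. It stands in the column that the layout keeps for −log10 p-values, and the sources used here do not state its scale otherwise. It is therefore read as evidence for a peak rather than as fold enrichment. The merged start and end were the outermost of both input peaks in 100% of rows. The columns that the layout keeps for signal value and q-value held -1 throughout. Whether the input lists came from the 2 DHX36 libraries or from splits of their reads is not given in the sources used here. They are therefore called the first and the second input list, in column order. The peaks had not been filtered on IDR. Read depth is unknown, since a peak list holds no read counts, and no control antibody list was used here.

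Coordinates are 1-based hg38 positions. Genes came from the RefSeq table of the matching assembly, which gives start and end for each gene but neither strand nor exons. From it 19970 protein-coding and 18177 lncRNA genes on chromosomes 1 to 22 and X were used. No genome sequence was used here. The planned search for G-quadruplex motifs in peaks and its matching on GC content were therefore not run, and the promoter was replaced by a window of 1 kb either side of both gene ends. A peak was counted at a gene end when it overlapped such a window by at least 1 bp. For the feature classes the peak centre was placed at a gene end, in a gene body or in intergenic sequence, in that order. Transcript starts inside a gene were not marked, so a peak there counted as gene body unless it lay at another gene's end. Expected overlap came from 200 random placements of the peaks, with width and chromosome kept. The chromosome length was taken as the largest annotated or peak coordinate, and assembly gaps were not removed. Placements can fall in gaps, where no peak can be called.

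The 26 gene lists, among them markers of blood, nerve, liver, muscle and mesenchymal cells, were fixed before the data were examined. The share of each list with an end peak was placed among 10000 random lists of the same size drawn from all protein-coding genes. A list was called above or below when its percentile was over 97.5 or under 2.5. Chance alone would put 1.3 of 26 lists outside. Because there was a single list of peaks, and peaks and genes are not replicates, no p-value was computed. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. No mean ± SD was computed, since it is not known whether the input lists stand for the 2 libraries.

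The rule for named genes was also fixed before the data were examined. It took DHX36 and every gene of a list made for promoter G-quadruplexes in the literature. It also took up to 4 genes of each other list with the highest signal at an end peak, and the 10 peaks with the highest signal. Also taken were 3 genes of the 9p21 region described as deleted in MCF-7, and members that were exceptions in lists with at most 3 exceptions. The divergent transcript comparison, the small RNA classes and the neighbouring-end comparison were added after the peaks had been seen. For the divergent transcripts, genes whose symbol plus the suffix -DT names a lncRNA were used where the gap between both was at most 5 kb and the gene was longer than 4 windows of 2 kb. The end facing the divergent transcript then marks the gene's 5′ end. Small RNA genes were counted when a peak lay within 250 bp of the gene. A peak was placed at a chromosome end when it lay within 50 kb of, or beyond, the outermost annotated gene.

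Alternatives were a window of 500 bp or 2 kb, the peak centre in place of any overlap, protein-coding genes only, peaks above the median signal, and merging of peaks within 500 bp. Peaks with a global IDR of at most 0.05, random placements within 100 kb of a gene, random lists matched on gene length in 10 bins, and peaks above the median of either input list were added after the data had been seen. The counting was tested on simulated data with 19970 genes and 10345 peaks. Random peaks gave a fold of 0.99 over the placements, and 100% of genes given an end peak were recovered. Of random lists of 40 genes, 4% were called, against 5% set by the percentile limits. Nearly all simulated peaks were placed at random, so few genes had an end peak and no list could be called below. That check therefore says nothing about lists called below. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.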

Results

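The series addressed where DHX36 sits on chromatin in MCF-7 breast cancer cells and what its rapid loss does to transcription. DHX36 is a DEAH-box helicase that unwinds G-quadruplexes, four-stranded structures of guanine-rich DNA and RNA. The data analysed were the DHX36 CUT&Tag peaks of untreated cells, a single list standing for a group of 2 libraries. It gives 10438 peaks with their signal in both input lists, a −log10 p-value by the layout of the list. It also gives their global irreproducible discovery rate (IDR). For a peak this estimates the rate of peaks that do not repeat between those lists, among all peaks ranked at least as high. Read depth is unknown, and whether the input lists stand for the 2 libraries is not known, so no replicate error is given.

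The DHX36 peaks were narrow. Their median width was 726 bp, with the middle 50% between 570 and 933 bp, and together they covered 8.21 Mb of hg38. Of all peaks, 10345 lay on chromosomes 1 to 22 and X, 5 on the mitochondrial genome, 4 on chromosome Y and 84 on unplaced or random sequences. The median signal was 12.1, and the range ran from 5.05 to 2072. Only part of the list ranked reproducibly: 4190 peaks (40.1%) had an IDR of at most 0.05, 2706 had an IDR of at most 0.01, and 2801 (26.8%) sat at the highest IDR in the list, 0.453. Across peaks, which are not independent replicates, the signals of the input lists had a Spearman rho of 0.71 and, on the log2 scale, a Pearson r of 0.80. The second input list was higher at 62.9% of peaks, with a median log2 ratio of 0.15 and an SD of 0.47 over peaks. Both correlations are over peaks found in both lists, which leaves out peaks seen in a single list.

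**Figure D1:**
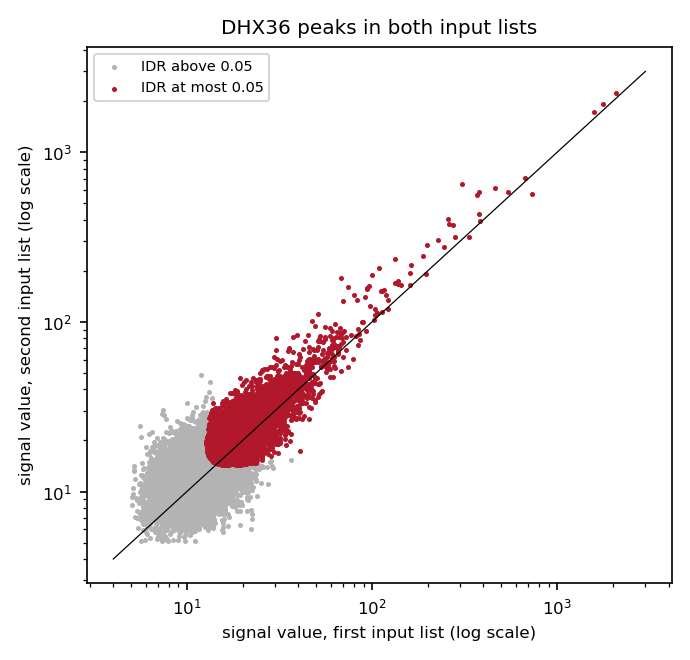
Signal of each DHX36 peak in the first input list (x axis) and in the second input list (y axis), both on log axes and in the authors' units, 1 point per peak, with a line of equal signal. Peaks with an IDR of at most 0.05 are drawn apart from the rest, and 62.9% of all peaks were higher in the second list.

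DHX36 peaks were concentrated at gene ends. Of the 10345 peaks on chromosomes 1 to 22 and X, 5735 (55.4%, exact 95% interval 54.5 to 56.4%) overlapped the window of 1 kb around an end of a protein-coding or lncRNA gene. Random placements gave 6.99% on average and between 6.34 and 7.55%, so the observed share was 7.93-fold higher. Random placement takes no account of open chromatin, which the transposase can cut whatever the antibody. No control antibody list was used, so this share is not shown to be specific to DHX36. Stronger peaks lay at gene ends more often: over 4 equal groups of peaks by rising signal the share was 48.6%, 53.8%, 58.2% and 61.2%. Random placement gave 6.72%, 6.78%, 6.99% and 7.68% for the same groups, so the fold over random was 7.22, 7.94, 8.33 and 7.96 and did not rise beyond the third group. By peak centre, 53.02% lay at a gene end against 5.20% of random placements, 29.3% in a gene body against 51.7%, and 17.7% in intergenic sequence against 43.1%. In all, 6127 of 19970 protein-coding genes (30.7%, 30.04 to 31.3%) had a peak at an end, against 2.32% by random placement. Of these, 5797 had it at a single end and 330 at both. With peaks at an IDR of at most 0.05 the number of genes was 2817.

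The gene table holds no strand, so genes with an annotated divergent lncRNA were used to tell the ends apart, since that transcript starts at the gene's 5′ side. Of 488 such genes, 217 (44.5%, 40 to 49%) had a DHX36 peak at the end facing the divergent transcript and 7 (1.43%, 0.579 to 2.93%) at the opposite end. Both shares come from the ends of the same 488 genes, so their intervals are not those of independent groups. Genes without a divergent lncRNA were not examined in this way. The summits sat at the start of the gene: over 213 summits within 1 kb, the median position was 83 bp outside the gene (a position of -83 bp), with the middle 50% from -263 to 108 bp, and 39.9% (33.3 to 46.8%) fell inside the gene body. At an IDR of at most 0.05 the shares were 17.01% and 0.205%. The limit on open chromatin given above holds for this contrast between ends too.

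**Figure D2:**
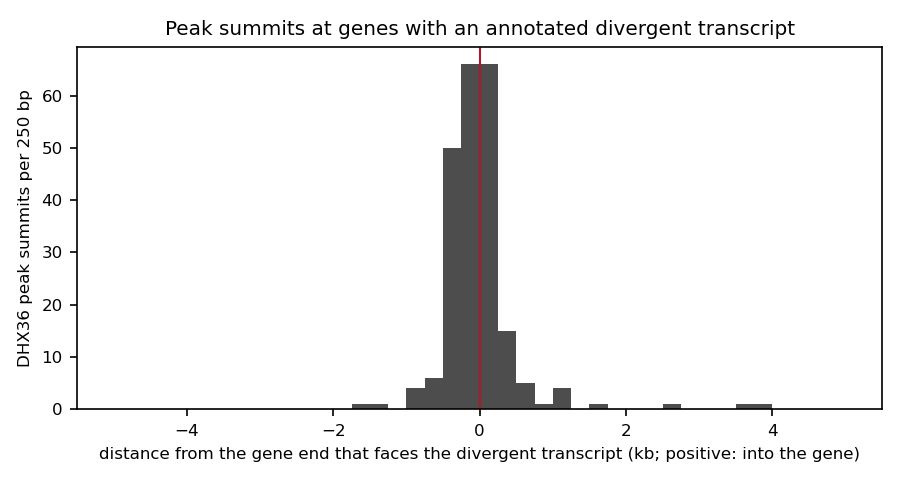
Number of DHX36 peak summits (y axis) by position relative to the end that faces the divergent transcript (x axis, negative outside the gene and positive inside it), in bins of 250 bp over the 488 genes with a divergent lncRNA. Summits gather at the gene's 5′ side, with a median position of -83 bp.

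Genes for splicing, DNA repair, the p53 response and G-quadruplex binding often carried DHX36 peaks. In the splicing list 52 of 73 genes (71.2%, 59.4 to 81.2%) had an end peak, led by SF3A2, a U2 snRNP subunit (signal 48.6 and 48.0 in the first and the second input list), HNRNPA1 (44.1 and 53.1), HNRNPA2B1 (30.7 and 29.6) and HNRNPC (28.7 and 39.1). Among DNA repair genes it was 28 of 40 (70.0%, 53.5 to 83.4%), with the damage kinase ATM (34.4 and 38.6), the mismatch repair gene MLH1 (27.2 and 35.2), MDC1 (30.4 and 27.0) and XRCC3 (25.4 and 30.3) highest. Known p53 target genes had peaks at 16 of 25 (64.0%, 42.5 to 82.0%), with the ribonucleotide reductase subunit RRM2B (54.5 and 59.9) highest, then PLK3 and DDB2. Helicases and binding proteins of G-quadruplexes had them at 21 of 34 (61.8%, 43.6 to 77.8%), led by the transcription factor SP1 (58.7 and 68.8), HNRNPA1, DDX5 (36.3 and 38.3) and HNRNPF (24.8 and 38.2). The DHX36 gene itself (chromosome 3, 154272546 to 154324487) had no peak at either end. Each of these lists lay above the range of random lists, at the 99.985th percentile or higher. Of the 87 named genes with an end peak in all lists, 35 shared that peak with the end window of another protein-coding gene, so its signal does not belong to the named gene alone. Here these were SF3A2 (with PLEKHJ1), HNRNPA1 (CBX5), HNRNPA2B1 (CBX3), ATM (NPAT), MLH1 (EPM2AIP1), XRCC3 (ZFYVE21) and DDX5 (CEP95).

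Housekeeping and growth-related genes also often had peaks. End peaks were found at 26 of 39 proteasome genes (66.7%), among them PSMB9 and PSMC5, and at 23 of 40 cell cycle genes (57.5%), among them CDK2 (47.1 and 54.0), CCNE2, CHEK1 and MCM7. The CDK2 peak lay past the gene's upper coordinate and also touched the end window of RAB5B, and the peaks at PSMB9 (TAP1), PSMC5 (FTSJ3), CCNE2 (NDUFAF6) and MCM7 (AP4M1) were shared likewise. Translation initiation genes had peaks at 31 of 55 (56.4%), with EIF3J highest (34.9 and 49.3). Cytosolic ribosomal protein genes had them at 46 of 85 (54.1%), with RPLP2 and RPLP0 highest, and mitochondrial ribosomal protein genes at 29 of 77 (37.7%), with MRPS18B highest (57.7 and 55.3). The RPLP2 peak was shared with PIDD1 and the MRPS18B peak with PPP1R10. For the mitochondrial list the percentile was 90.4, inside the random range. Replication histone genes had peaks at 39 of 73 (53.4%), but these genes lie in pairs and the 39 shared 23 peaks, as at H2AC11 and H2BC11 (27.1 and 47.9). RNA polymerase II, general transcription factor and Mediator genes reached 42 of 83 (50.6%), with MED11 and CCNT1 highest. Immediate early genes reached 15 of 30 (50%), with the growth factor responsive EGR1 (40.8 and 38.8), MCL1, JUND and KLF10 highest. Each of these lists except the mitochondrial one lay above the random range, at percentiles of 98.6 or more. Random lists drew genes singly, so the histone percentile takes no account of the pairing. Whether the histone list would stay above with each peak counted once was not tested. With peaks at an IDR of at most 0.05 the proteasome (percentile 97.0), translation initiation (88.7), RNA polymerase II (85.1) and immediate early (96.5) lists came inside it. The RNA polymerase II list also came inside it with peaks above the median signal (97.2), and with peaks above the median of the second input list so did that list (85.1) and the ribosomal protein list (95.96). With peaks above the median of the first input list the translation initiation (94.5) and immediate early (95.97) lists came inside it, as did the immediate early list with the 500 bp window (95.3).

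**Figure D3:**
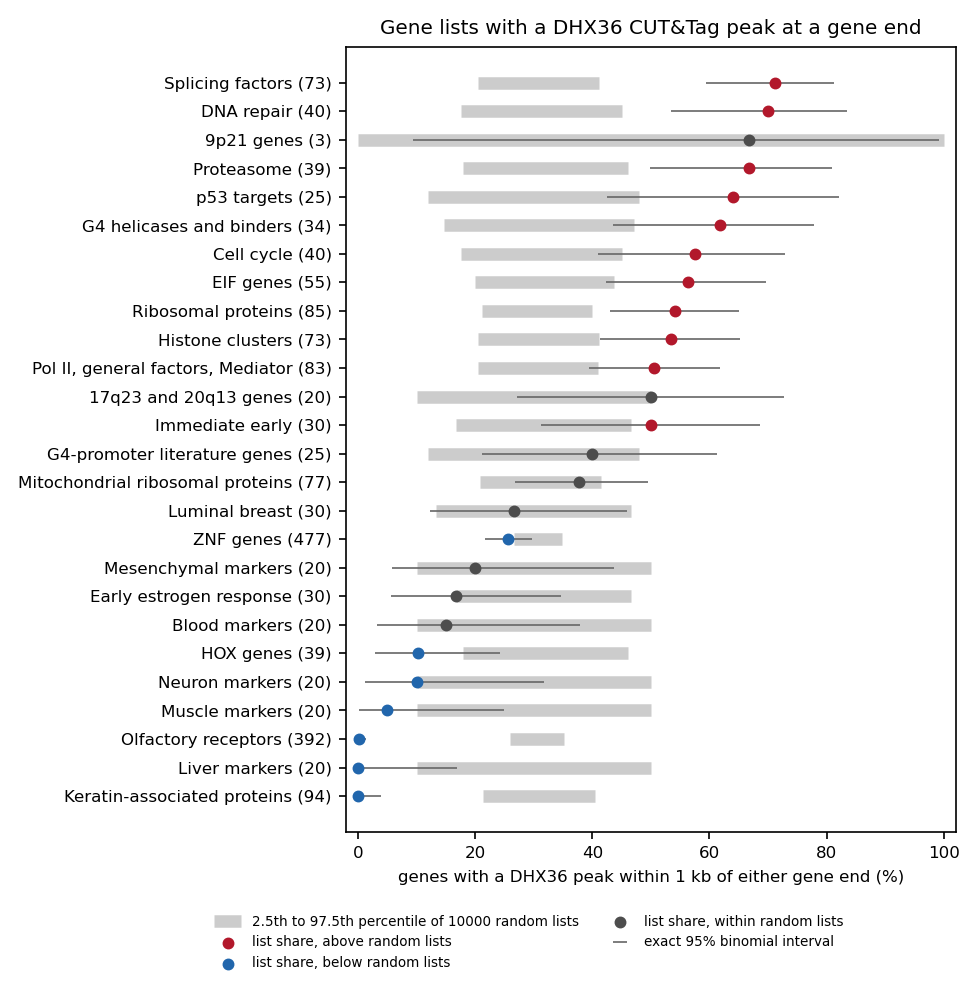
Share of genes with a DHX36 peak within 1 kb of either gene end (x axis, percent) for the 26 gene lists (y axis, number of genes in brackets). Points are list shares with exact 95% binomial intervals, grey bars span the middle 95% of 10000 random lists of that size, and colour shows the 11 lists called above, 7 called below and 8 within by percentile. The neuron point, called below, sits on the lower limit of its bar.

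A list made for promoter G-quadruplexes in the literature did not stand apart as a group. Which of its genes hold a G-quadruplex in the promoter was not examined. Of the 25 genes, 10 (40%, 21.1 to 61.3%) had an end peak, the 84.0th percentile of random lists, and 7 had a peak with an IDR of at most 0.05 (96.7th percentile). The peak at MYC lay on chromosome 8 from 127735219 to 127736207, over the gene's lower coordinate at 127735434, with a signal of 16.2 and 16.8 and an IDR of 0.0208. STAT3 (38.5 and 38.3; chromosome 17, 42388030 to 42389095) and MCL1 (30.2 and 39.7; chromosome 1, 150578921 to 150580071) had the strongest peaks of the list. TOP1 (25.1 and 26.1), TYMS (23.3 and 15.7), KRAS (13.3 and 20.8; chromosome 12, 25250529 to 25251528) and YY1 (13.3 and 20.2) also had an IDR of at most 0.05. The peaks at PDGFRB (IDR 0.0818), BCL2L1 (0.0743) and ADAM10 (0.453) did not, and the PDGFRB peak also touched the end of its neighbour CSF1R. That peak lay outside PDGFRB, below its lower coordinate. Strand was not used, so the ends counted for this list are not shown to be promoters. No end peak was listed for KIT, BCL2, VEGFA, HIF1A, PDGFA, PDGFRA, RET, TERT, MYB, RB1, HRAS, NRAS, SRC, ILK or CCND3.

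Breast lineage genes lay within the random range. Luminal breast genes had an end peak at 8 of 30 (26.7%, percentile 33.1), with MUC1 (33.2 and 38.5), ELF3 and ERBB3 highest, where the MUC1 peak was shared with THBS3 and the ERBB3 peak with PA2G4. The ELF3 and ERBB3 peaks lay past the upper coordinate of each gene. Strand was not used, so these ends are not shown to be promoters. Early estrogen response genes had one at 5 of 30 (16.7%, percentile 4.27), among them KDM4B, MYC, TIPARP and SIAH2. With the 2 kb window that list fell below the random range (percentile 2.35). Of 20 genes of the 17q23 and 20q13 segments described as amplified in MCF-7, 10 (50%) had an end peak. Among them were BCAS3 (25.02 and 36.3), CSE1L, BRIP1 and RPS6KB1, the last with a peak shared with TUBD1. These 10 genes had 9 distinct peaks, so the share and its percentile count a shared peak more than once. The list also holds PRKCE, which lies on chromosome 2; without it 9 of 19 genes (47.4%) had an end peak, a percentile of 93.5. The full list's percentile of 96.1 rose past the upper limit with peaks at an IDR of at most 0.05 (98.96), with peaks above the median signal (99.2) and with the 2 kb window (97.7). Without PRKCE it did so at the IDR limit (99.3) and above the median signal (99.5) but not with the 2 kb window (95.9). The 9p21 genes, described as deleted in this line, had end peaks at CDKN2A (7.52 and 10.6, IDR 0.453) and CDKN2B (19.9 and 8.35, IDR 0.25), both with an IDR above 0.05, and none at MTAP. Another peak lay inside CDKN2A, away from its outer coordinates, on chromosome 9 from 21974749 to 21975217 (16.97 and 16.6, IDR 0.0196). Whether it lay at a transcript start inside the gene was not examined.

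Liver, muscle and neuron genes and several gene families had end peaks less often than random lists. Olfactory receptor genes had an end peak at 1 of 392 (0.255%, 0.00646 to 1.41%), OR2V2 with a signal of 5.78 and 7.20, and keratin-associated protein genes at 0 of 94 (0 to 3.85%). Liver genes had none of 20 (0 to 16.8%) and muscle genes 1 of 20, TNNC2, whose peak was shared with SNX21. Neuron genes had 2 of 20, GRIN1 and TUBB3, with peaks shared with LRRC26 and MC1R. HOX genes had 4 of 39 (10.3%), where HOXC4, HOXC5 and HOXC6 shared a single peak (22.1 and 37.1) and HOXC13 had its own. With the 500 bp window the HOX share was 2.56%. ZNF genes had 122 of 477 (25.6%, 21.7 to 29.7%), led by ZNF131 (60.7 and 88.6) and ZNF687. Each of these 7 lists had a percentile under 2.5, but the share of the neuron list (10%, percentile 1.8) equalled the lower limit of its random range. At an IDR of at most 0.05 the ZNF (percentile 6.97), neuron (12.7) and HOX (25.8) lists were no longer under 2.5, and with peaks above the median signal the same 3 lists were not either (12.4, 7.2 and 12.9). The ZNF list also left that side with the 500 bp window (3.34), and the neuron list with the 500 bp (2.67) and the 2 kb window (11.4), where its share was 20%. Blood genes (3 of 20: HBA1, CSF1R and SPI1) and mesenchymal genes (4 of 20: COL1A1, ACTA2, VIM and PDGFRB) lay within the random range. CSF1R and PDGFRB had the same peak, which counts in both lists.

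Many of the strongest DHX36 signals lay in classes of position that can hold sequence in several copies. The highest on chromosomes 1 to 22 and X (signal 1592) lay on chromosome 1 from 633456 to 634173, within 1 kb of the mitochondrial-like pseudogene MTATP8P1, and the next (672) on chromosome 1 from 629646 to 630034 near MTND2P28. Peaks at the ends of chromosomes X (567), 22 (540), 3 (381), 1 (371), 12 (316) and 5 (305) were also among the top 10, as was a peak on chromosome 4 from 190122541 to 190123092 (380). The remaining peak (464) lay on chromosome 1 from 31431753 to 31432184, 2.77 kb from SERINC2. The mitochondrial genome, unplaced sequences, chromosome ends, ribosomal RNA genes and mitochondrial-like pseudogenes together held 128 peaks (1.23% of the list) but 25 of the 50 with the highest signal (50%, 35.5 to 64.5%). Their median signal was 30.6 against 12.03 for the other 10310 peaks. The classes were assigned by position, and whether each peak lies in sequence with several copies was not examined. Reads from sequence with several copies cannot be assigned with certainty to a single position.

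The number and density of peaks varied between chromosomes. Chromosome 1 held 1257 peaks (5.05 per Mb) and chromosome 17 held 842 (10.1 per Mb). Chromosome 19 was the densest, with 658 peaks and 11.2 per Mb, but 28.5% of its protein-coding genes had an end peak. The share of protein-coding genes with an end peak was 40.4% (37.5 to 43.3%) on chromosome 17, 37.0% on chromosome 12 and 33.5% (31.4 to 35.6%) on chromosome 1, and it was lowest on chromosomes X (16.04%), 4 (19.1%), 13 (20.7%) and 18 (21.5%). The densest windows of 1 Mb held 43 peaks each, on chromosome 17 from 75000001 to 76000000 and on chromosome 19 from 1000001 to 2000000. On chromosome 1 the windows from 123000001 to 124000000 and from 124000001 to 125000000, with 0 protein-coding genes each, held 35 and 30 peaks. Whether these windows hold repeated sequence was not examined, and the classes counted above did not include centromeres. The share given for those classes may therefore leave out peaks in repeats, and it may include single-copy sequence.

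**Figure D4:**
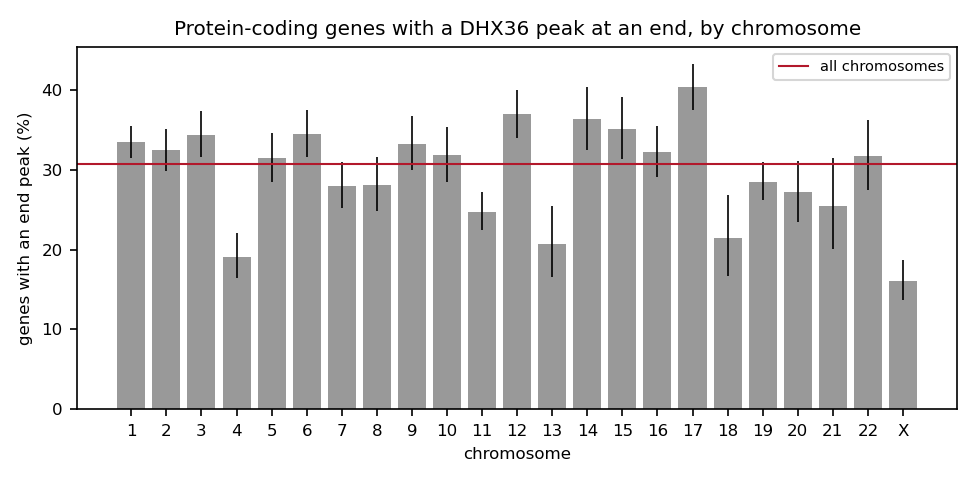
Share of protein-coding genes with a DHX36 peak at an end (percent) on each chromosome, with exact 95% binomial intervals and a line for the share over all chromosomes. Chromosome 17 stands highest at 40.4% and chromosome X lowest at 16.04%, against 30.7% over all chromosomes.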

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

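The IDR limit, the length-matched lists, the placements near genes and the rankings by a single input list were chosen after the data had been seen. An IDR of at most 0.05 left 4190 peaks in place of 10438. The share of peaks at gene ends moved beyond its interval under 6 alternatives and stays at 55.4% by construction with placements within 100 kb of a gene. It was 59.7% above the median signal, 52.3% with 500 bp, 60.2% with 2 kb, 53.02% by peak centre, 49.2% with protein-coding genes only and 60.7% at an IDR of at most 0.05. The fold over random placement lay between 5.38 and 12.1 across these settings. The intergenic share fell from 17.7% to 16.2% at an IDR of at most 0.05 and to 16.3% above the median signal. Lists above random numbered 8 to 12 against 11, and at the IDR limit 8 were above, of which 7 were among the 11. Lists below random numbered 4 in place of 7 above the median signal, 4 at the IDR limit, and 4 above the median of either input list, each time among the same 7; the cause was not tested. They numbered 5 with 500 bp, all among the 7, and 7 with 2 kb, of which 6 were among the 7. With length matching all 11 and all 7 kept their side. The neuron list stayed below only with length matching, and the ZNF list only with that and with 2 kb. The share of divergent-transcript genes with a peak at the facing end was 43.0% with 500 bp and 44.9% with 2 kb, and 17.01% at the IDR limit, where fewer peaks enter. No paired analysis was possible because the only list joins both inputs and no result comes from a test between groups. Other settings fixed before the data were examined, on motif loops, motif position, summit windows, shuffled sequence and GC matching, and on the 5′ end of any transcript, were not run, since no genome sequence or strand was used here. Random lists without matching became the main setting for the same reason. Unknown read depth means that a gene end without a peak is not shown to lack DHX36.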

Other observations

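The tests of the 9p21 pattern, of chromosome 1 alone and of the 17q23 segment were chosen after the results had been seen, as were the counts of small RNA genes and neighbouring ends. DHX36 peaks were frequent at tRNA and snRNA genes. Of 443 tRNA genes, which RNA polymerase III transcribes, 132 (29.8%, 25.6 to 34.3%) had a peak within 250 bp, against 0.614% by random placement. Of 154 snRNA genes 43 (27.9%, 21 to 35.7%) had a peak, against 0.831%, and among genes of the U1 spliceosomal RNA it was 14 of 21. At an IDR of at most 0.05 the shares were 12.6% for tRNA and 19.5% for snRNA genes. Named examples, chosen after their values were seen, were RN7SK, the RNA that holds the elongation factor P-TEFb inactive (signal 34.5 in the first and 22.4 in the second input list, chromosome 6, 52995070 to 52995908), RNU5B-1 (27.0 and 34.6), RNU7-1, which serves histone mRNA processing (15.2 and 17.6), and SNORD3A, the U3 RNA gene (102.9 and 103.03). snoRNA genes as a class had few peaks, 13 of 1196 (1.09% against 0.517%), and miRNA genes had 77 of 1911 (4.03% against 0.570%). At an IDR of at most 0.05 the shares were 0.753% for snoRNA and 1.57% for miRNA genes. Many of these genes exist in near-identical copies, so the copy that gave the reads is uncertain. Open chromatin may give peaks at small RNA genes too, which cannot be told apart from DHX36 binding without a control antibody list.

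Genes with a neighbour close by had peaks more often. Among 5709 protein-coding genes with another protein-coding gene's end within 1 kb, 50.2% (48.9 to 51.5%) had an end peak, against 22.9% (22.2 to 23.6%) of the other 14261. A single peak in such a gap counts for both genes. By gene length the share was 17.8% in the shortest of 10 equal groups, rose to 36.6% in the seventh and was 22.3% in the longest.

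Gene families differed in how many members carried a DHX36 peak, from 0 of 94 keratin-associated protein genes to 71.2% of splicing genes. Gene length, which brings both windows close together in short genes, is argued against as the whole cause: 100% of the 11 lists above random stayed above random lists matched on length. Open chromatin at active genes, which the transposase can cut whatever the antibody, may give the same contrast. It cannot be told apart from DHX36 binding here, since 0 control-antibody lists were used. The random lists were also not matched on close neighbours. Among genes with another protein-coding gene's end within 1 kb, 50.2% had an end peak, against 22.9% of the others. Whether this accounts for the contrast between lists was not tested, and no biological explanation was tested.

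Chromosomes 1 and 17 held the most peaks. For chromosome 1 the share of genes with an end peak was 1.09 times the genome-wide share. Gene number could thus account for its peaks at gene ends. For chromosome 17 the ratio to the genome-wide share was 1.32, above the limit of 1.2 set beforehand, which argues against gene number alone. These ratios leave out peaks away from gene ends, 600 of 1257 on chromosome 1 and 397 of 842 on chromosome 17. The amplified 17q23 segment alone is argued against too, since chromosome 17 genes more than 5 Mb outside the span of the listed amplified genes had a share of 40.1% (37.1 to 43.1%), a ratio of 1.31. Extra copies in general cannot be told apart from other causes: the amplified list reached the percentile 96.15 among length-matched lists, within the random range (92.7 without PRKCE, which lies on chromosome 2). Without PRKCE and without length matching it lay above that range at an IDR of at most 0.05 (99.3) and with peaks above the median signal (99.5) or the median of the first (98.1) or the second (99.4) input list, and no copy number of these cells was used.

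Peaks lay at the ends of CDKN2A (IDR 0.453) and CDKN2B (0.25), and another (16.97 and 16.6, IDR 0.0196) inside CDKN2A, although these genes are described as deleted in MCF-7. The segment from 21802636 to 22009313 on chromosome 9 held 3 peaks, against a mean of 0.703 and a maximum of 5 over 1000 random placements, and 3.1% of placements held as many. This share decides neither for nor against peaks scattered by chance over the genome. A second count, of placements with an end peak at 2 or more of the 3 genes (0.1%), restates the observation and decides nothing, and 2 of 3 genes was only the 87.8th percentile of random lists. DNA of the segment in some of these cells, or in other human DNA in the libraries, may be the source, which cannot be told apart with 0 files on copy number or genotype used.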
